A study of Homo sapiens with 4 samples.

How the data were processed

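The samples were 4 chromatin immunoprecipitation (ChIP-seq) libraries from LS174T cells, an established human colorectal adenocarcinoma line, engineered so that doxycycline switches on murine SNAIL1 carrying a hemagglutinin (HA) tag. SNAIL1 is a zinc-finger repressor that drives epithelial-mesenchymal transition (EMT), the loss of epithelial character. Per the labels' protocols, 2 libraries came from cells given 0.1 mg/ml doxycycline for 6 h (induced 1 and induced 2) and 2 from cells left without it (uninduced 1 and uninduced 2). All were precipitated with an anti-HA antibody from formaldehyde-fixed chromatin sheared to 100 to 550 bp, and sequenced as single reads of 50 bp. Input chromatin was sequenced as reference, per the series' design text. That text calls the 2 libraries of each condition biological replicates; whether these were separate cultures is not given in the sources used here, so the spread between them may be partly technical. The group and replicate number of each library were taken from its title.

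The submitters' processing notes name Trimmomatic 0.36, BWA 0.7.15, MACS2 2.1.1.20160309 and the human build hg19. The role and order of Trimmomatic and BWA, the treatment of duplicate reads, the peak threshold and the control library paired with each ChIP library are not given in the sources used here. The authors deposited 1 narrowPeak list per library, so peaks were called per sample and not on pooled replicates. In each list the authors give the peak's start and end, the offset of its summit, its fold enrichment over the local background, the −log10 p and −log10 q of the peak, and a score. The deposited score was 10 times the −log10 q, rounded down, in every line of all 4 lists. The peak numbers in each list ran without gaps. These values belong to single peaks and were used to describe, rank and filter peaks within a list. The files hold no read totals, so the depth of each library is unknown from them directly.

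Read pileups were recovered from the deposited values. MACS2 writes fold enrichment as the summit pileup over the local background, each raised by a pseudocount of 1, and p as the Poisson tail above the pileup. Solving both for each peak gave a whole pileup within 0.0005 of the listed −log10 p for 1338 of 1338 peaks of induced 2, 5 of 5 of uninduced 1 and 11 of 11 of uninduced 2. In induced 1 the pileups had been scaled down to a smaller control library, and solving with that scale gave a whole pileup for 823 of 823 peaks. The scale of the pileups gave the depth of induced 1 relative to its control as 1.40. In the other lists this ratio was the step of the backgrounds, 0.904 for induced 2, 0.879 for uninduced 1 and 0.755 for uninduced 2. Backgrounds were whole numbers of control reads at 396 of 823 peaks of induced 1, 731 of 1338 of induced 2, 4 of 5 of uninduced 1 and 8 of 11 of uninduced 2, so the uninduced ratios rest on few peaks. The genome-wide background, which MACS2 uses as a floor, was 6.00 reads in induced 1 (at 48 peaks) and 4.15 in induced 2 (at 36 peaks), so induced 1 was sequenced 1.45 times as deeply as induced 2 if the same fragment and genome lengths were set for both. Pileups are numbers of extended reads covering the summit, and their 95% exact Poisson intervals cover counting error only. On simulated peaks the recovery returned 100% of the pileups, over 293 peaks of the induced 2 type and 192 of the induced 1 type.

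Peaks of 2 lists were called shared when they overlapped by at least 1 bp (Python 3.11.15 and scipy 1.17.1, with the number of shared peaks checked in bedtools 2.31.1). Where 1 peak met several, the largest overlap was kept. Chance overlap came from 1000 circular shifts of 1 list within each chromosome, with the furthest peak of the 4 lists as the chromosome's end, and from 1000 draws that moved each peak by 5 to 100 kb. On simulated lists with 400 planted overlaps, 401 were found, against 1 with none planted. Shares have exact (Clopper-Pearson) 95% intervals. Numbers of peaks per library were compared by an exact permutation test, and fold enrichments across shared peaks by Spearman's rho with 100000 permutations. Differences in pileup between replicates were tested per shared peak with an exact binomial test against the overall pileup ratio, with Benjamini-Hochberg adjustment. Peaks per chromosome were tested with an exact binomial test against length, with Benjamini-Hochberg adjustment over 23 chromosomes. The share of peaks in the first 5 Mb of chromosomes was tested, one-sided, with 10000 uniform placements, leaving out chromosomes 13, 14, 15, 21 and 22, whose short arms hold little unique sequence. This test called 5% of simulated uniform lists at 0.05. Runs of peaks at most 20 kb apart were set against 200 uniform placements.

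Before the data were examined, the rule for named peaks was fixed as the 15 shared peaks with the highest mean percentile of fold enrichment in the induced lists, every uninduced peak, and the 3 strongest peaks of each induced list that the other lacked. The settings varied were a −log10 q of at least 5, a fold of at least 5, a reciprocal overlap of 50%, summits within 100 bp, merged intervals, the longer list shortened to the length of the other, chromosomes 1 to 22 and X only, each library left out and a replicate block. The pileup recovery, the binomial test of pileups, all counts by chromosome, chromosome end and run, and the shifts by 5 to 100 kb were chosen after seeing the data, as were the tests of explanations. Gene annotation of peaks, the binding of 5 fixed gene lists and motif counts at summits were planned, but they needed an hg19 genome and annotation, which were not used here, so peaks are named by hg19 position, counted from 1. A reference gene table of another build was not used.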

Results

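Binding of HA-tagged SNAIL1 to chromatin was mapped in LS174T colorectal cancer cells to locate the sites this EMT-inducing factor occupies within 6 h of its induction. The data comprise 4 peak lists, 2 from induced and 2 from uninduced cells. Total read numbers were unknown. Pileups recovered from the listed values gave a median of 51 reads at the summits of induced 1 and 35 at those of induced 2, and the lowest called pileups were 28 and 17. Pileups of induced 1 are given, here and below, before they were scaled down by the ratio of 1.40 for peak calling. They are thus not the levels at which its peaks were called.

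Induced cells carried many SNAIL1-HA peaks and uninduced cells few. Induced 1 held 823 peaks and induced 2 held 1338, a mean of 1080.5 ± 364 (SD, n = 2). Uninduced 1 held 5 and uninduced 2 held 11, a mean of 8.0 ± 4.24 (SD, n = 2), so the mean was 135 times higher after induction. This ratio rests on the few uninduced peaks, of which 4 in uninduced 2 had folds of only 1.30 to 1.35, and was 216 without uninduced 2. Both induced lists exceeded both uninduced lists. With 2 libraries against 2, the exact two-sided permutation test cannot go below p = 0.333, which is the value obtained. At a fold of at least 5, the lists held 486 and 646 peaks in induced cells and 3 and 6 in uninduced cells. The peaks were narrow, with median widths of 338 bp in induced 1 and 336.5 bp in induced 2. Their median fold enrichment was 5.33 in induced 1 and 4.91 in induced 2.

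**Figure D1:**
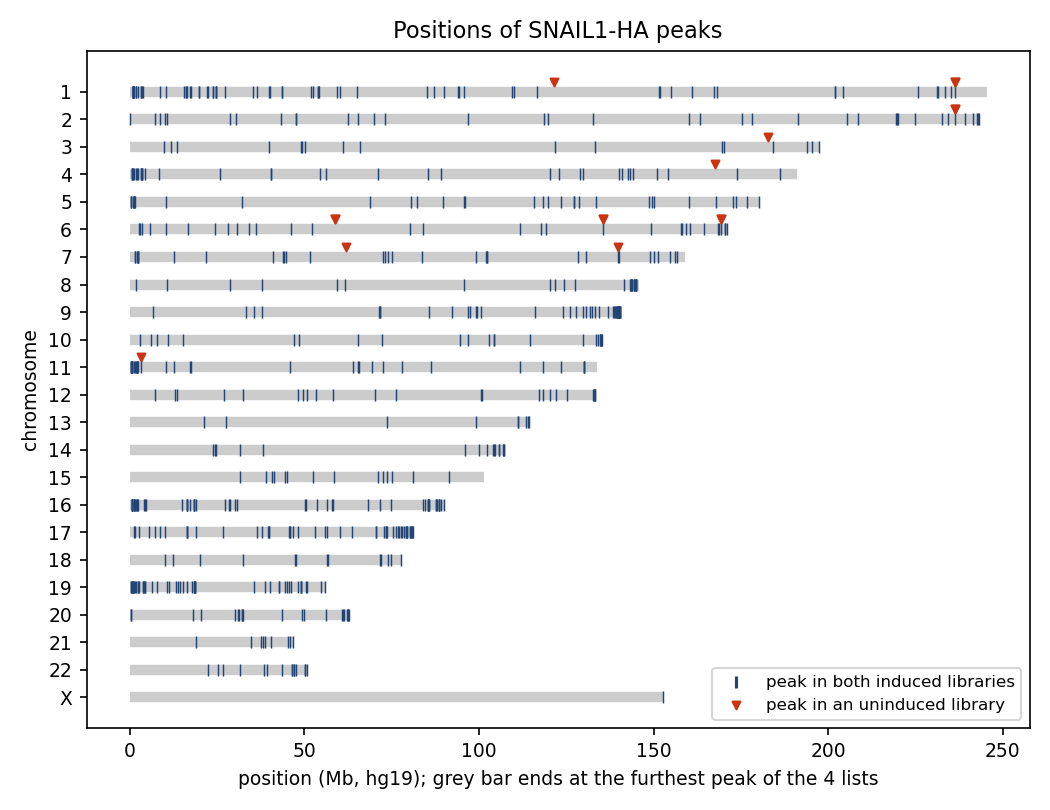
Positions along each hg19 chromosome (x axis, Mb) of the 661 peaks found in both induced libraries (dark ticks) and of the 16 peaks of the uninduced libraries (red triangles), on grey bars that end at the furthest peak of the 4 lists. Shared peaks crowd at several chromosome ends and 1 lies on chromosome X.

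The 15 shared sites highest in mean percentile of fold lay on chromosomes 1, 2, 5, 7, 16, 17, 19 and 20. Fold depends on the control background as well, so this is not a ranking by ChIP reads. The shared peak on chromosome 1 at 54303994 to 54304414 had 152 and 134 reads but is not among them. The peak on chromosome 5 at 95998079, which is, had 101 and 109. The first by mean percentile was on chromosome 17 from 7165563 to 7166045, with 19.3-fold enrichment in induced 1 and 18.4-fold in induced 2. Its summit was covered by 196 reads (95% interval 170 to 225) in induced 1 and 155 (132 to 181) in induced 2. The control gave backgrounds there of 6.30 and 8.25 control reads. ChIP and control reads are both given before scaling for depth, so their ratio is not the listed fold. Chromosome 1 supplied 5 of the 15. These were the peaks at 89990426 to 89991029 (20.4-fold and 17.3-fold), 236332266 to 236332733 (15.1-fold and 25.3-fold), 1111033 to 1111956 (16.7-fold and 16.0-fold), 154973524 to 154973959 (15.1-fold and 17.9-fold) and 22587327 to 22587823 (14.5-fold and 14.2-fold). The only one on chromosome 7 was at 44788294 to 44788919 (15.2-fold and 15.9-fold), where 148 and 130 reads covered the summit. On chromosome 20, the peak at 400193 to 400702 had 13.8-fold and 14.7-fold enrichment and the peak at 31124607 to 31125053 had 13.05-fold and 15.8-fold.

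The remaining sites of this group had similar folds. The peak on chromosome 19 at 1528377 to 1528933 reached 13.5-fold and 16.5-fold, and the peak on chromosome 16 at 89913888 to 89914359 reached 13.7-fold in each library. Chromosome 5 held a peak at 95998079 to 95998607 (13.8-fold and 14.1-fold) and another at 89854450 to 89855025 (13.5-fold and 14.2-fold). Chromosome 2 held a peak at 236279577 to 236280159 (16.9-fold and 12.6-fold) and another at 7171774 to 7172240 (12.8-fold and 14.5-fold). Across the 15 sites the summits of the replicates lay 2 to 83 bp apart. Control backgrounds, in control reads before scaling for depth, ranged from 4.29 to 8 in induced 1 and from 5.10 to 10 in induced 2. The value of 4.29 is the genome-wide background of induced 1, which is 6.00 on the scale of its ChIP reads. Of the 15, only the peak at 236332266 on chromosome 1 and the peak at 236279577 on chromosome 2 also appeared in uninduced cells.

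Most sites of the shorter induced list recurred in the longer one. Of the 823 peaks of induced 1, 661 (80.3%, 95% interval 77.4 to 83.0) overlapped a peak of induced 2, and 660 of the 1338 peaks of induced 2 (49.3%, 46.6 to 52.0) overlapped a peak of induced 1. Circular shifts of induced 2 gave a mean overlap of 0.389 peaks and at most 3 in 1000 draws. Shifts of each peak by 5 to 100 kb gave a mean of 2.18 and at most 8. The summits of shared peaks lay a median of 23 bp apart, and 617 of the 661 (93.3%) lay within 100 bp. At a fold of at least 5 in both lists the number of shared peaks was 342.

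Sharing rose with enrichment. With each list divided by fold enrichment into 4 groups of about equal size, 65.5% of the weakest group of induced 1 (58.6 to 72.0) were found in induced 2, against 99.0% (96.5 to 99.9) of the strongest. For induced 2 the shares were 26.5% (21.8 to 31.5) and 88.3% (84.4 to 91.6). Shared peaks had a median fold of 5.68 in induced 1, against 4.53 for unshared ones. The corresponding medians in induced 2 were 6.01 and 4.38.

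**Figure D2:**
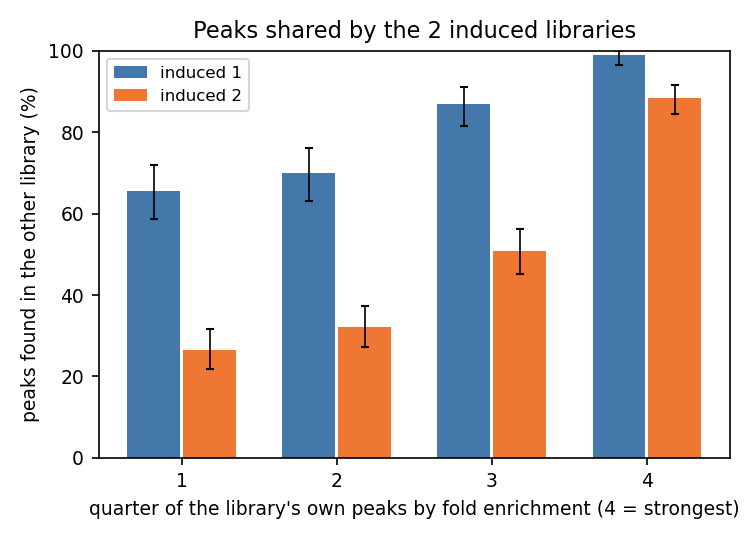
Percentage of each induced library's peaks found in the other induced library (y axis), by group of the library's own peaks ranked by fold enrichment (x axis, 4 is the strongest), with exact 95% binomial intervals as error bars. The share reached 99.0% in the strongest group of induced 1 and 88.3% in that of induced 2.

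Fold enrichment of the 661 shared peaks correlated between the induced libraries across peaks, with Spearman's rho of 0.585 (permutation p = 1e-05, the smallest that 100000 permutations can give) and Pearson's r of 0.701. Peaks are not independent replicates, so this p describes these 2 libraries. Summit pileups of shared peaks were 1.23 times higher in induced 1 in total, less than the depth ratio of 1.45 inferred from the genome-wide backgrounds. After that overall ratio was taken out, none of the 661 peaks passed an exact binomial test of pileup between the replicates with Benjamini-Hochberg adjustment, and 19 had an unadjusted p under 0.05. At the median total of 100 reads, a pileup had to be higher in induced 1 by 1.58 times beyond the overall ratio of 1.23 for an unadjusted p under 0.05, and by 2.44 times beyond it for a single peak to pass the adjustment, so smaller differences were not detectable. The median absolute difference was 0.19 on the log2 scale. This test takes reads as independent molecules, covers counting error only and leaves out peaks found in 1 replicate alone.

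**Figure D3:**
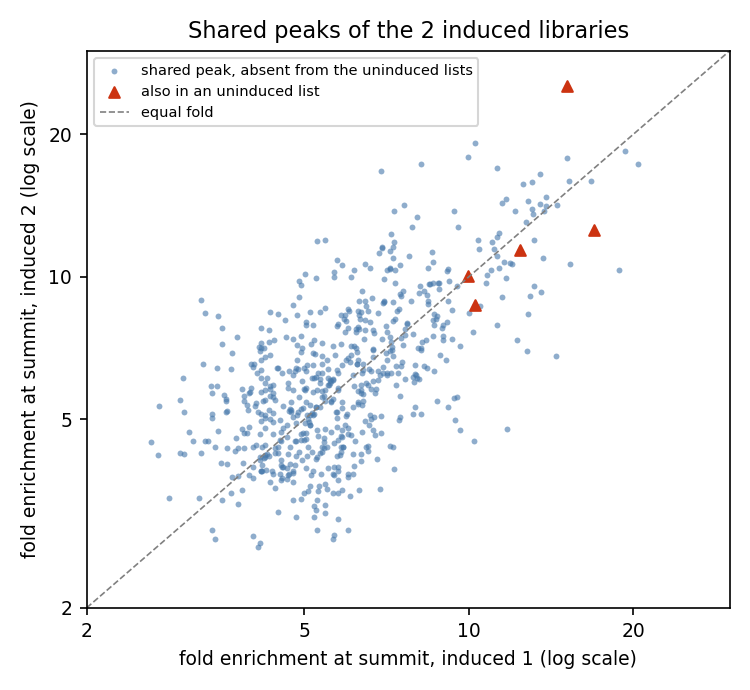
Fold enrichment at the summit of the 661 shared peaks in induced 1 (x axis, log scale) and induced 2 (y axis, log scale), with equal fold as a dashed line and red triangles for peaks that also appear in an uninduced list. Each point is 1 peak, and Spearman's rho was 0.585.

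Several strong sites were found in 1 induced library only. In induced 2 the peak with the highest fold of the list was of this kind, on chromosome 6 from 135502324 to 135503572, with 29.3-fold enrichment and 174 reads at its summit. It was also present in both uninduced lists. The next were on chromosome 2 at 122777062 to 122777431 (11.2-fold, 62 reads) and on chromosome 3 at 156838324 to 156838740 (9.91-fold, 50 reads). The strongest peaks found in induced 1 only were weaker. They lay on chromosome 10 at 72237394 to 72237778 (7.42-fold, 63 reads), chromosome 19 at 49242203 to 49242534 (6.88-fold, 59 reads) and chromosome 16 at 3696321 to 3696601 (6.63-fold, 55 reads). In the strongest of the 4 groups of each list, 2 peaks of induced 1 and 39 of induced 2 were unshared.

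The lists of uninduced cells held 16 anti-HA peaks, and 11 of these overlapped a peak of an induced library. Circular shifts gave a mean of 0.004 such overlaps and at most 2. The uninduced libraries had 4 sites in common. The site on chromosome 1 near 236332334 had 8.77-fold and 8.37-fold enrichment in uninduced 1 and uninduced 2, with 54 and 69 reads. The site on chromosome 2 near 236279756 had 4.73-fold and 8.08-fold, and the site on chromosome 6 near 169313392 had 9.06-fold and 5.28-fold. In the induced lists these 3 sites had 15.1-fold and 25.3-fold, 16.9-fold and 12.6-fold, and 10.2-fold and 8.73-fold enrichment in turn. The fourth was the chromosome 6 site near 135502454, at 14.4-fold and 6.47-fold, with 102 and 47 reads, which induced 1 lacked.

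Uninduced 2 alone shared 3 further sites with induced cells. Those on chromosome 11 at 3164184 to 3164488 (4.51-fold) and chromosome 7 at 139709600 to 139709860 (5.03-fold) were in both induced lists, with 9.98-fold and 10.0-fold, and 12.4-fold and 11.4-fold enrichment. The site on chromosome 3 at 182833997 to 182834246 (5.11-fold) was in induced 2 only, at 5.52-fold. The other 5 uninduced peaks overlapped no induced peak. They were a 3.16-fold peak of uninduced 1 on chromosome 4 at 167501205 to 167501539, and 4 peaks of uninduced 2 with folds of 1.30 to 1.35. These 4 began at 121484598 on chromosome 1, 58776440 and 58778339 on chromosome 6, and 61968983 on chromosome 7. Their summits had 476 to 500 ChIP reads over 477 to 500 control reads before scaling, against 8 to 18 control reads at the other 7 peaks of that list. Peaks also found in uninduced cells made up 0.608% of induced 1 (5 peaks) and 0.523% of induced 2 (7 peaks).

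The binding sites were unevenly spread over the chromosomes. Chromosome 19, which is rich in genes, had the highest density in both libraries, with 11.4 peaks per 10 Mb (95% Poisson interval 8.78 to 14.6) in induced 1 and 15.0 (11.9 to 18.5) in induced 2. Its 50 shared peaks were 4.07 times the number expected from its length (exact binomial test, adjusted p = 4.6e-15). Chromosomes 17 (51 shared peaks, 2.87 times), 16 (54 peaks, 2.74 times) and 1 (73 peaks, 1.36 times) were also above their length, with adjusted p of 3.2e-10, 3.6e-10 and 0.027. Chromosomes 3 (17 peaks, 0.393 times), 13 (9 peaks, 0.359 times) and X were below it, with adjusted p of 2.8e-05, 0.0013 and 1.2e-12. Chromosome X held 2 peaks in each induced library, against 41.6 and 67.7 expected from length, and 1 of them was shared. That peak, from 152663408 to 152664037, was strong, with 13.02-fold and 13.9-fold enrichment. Chromosome Y, which was not among the 23 chromosomes tested, held 1 unshared peak of induced 1, from 635475 to 635956 (4.51-fold). These 7 chromosomes passed the threshold in the same direction in each induced list alone. Peaks are the units of this test, so it describes the lists and not the spread between cultures.

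**Figure D4:**
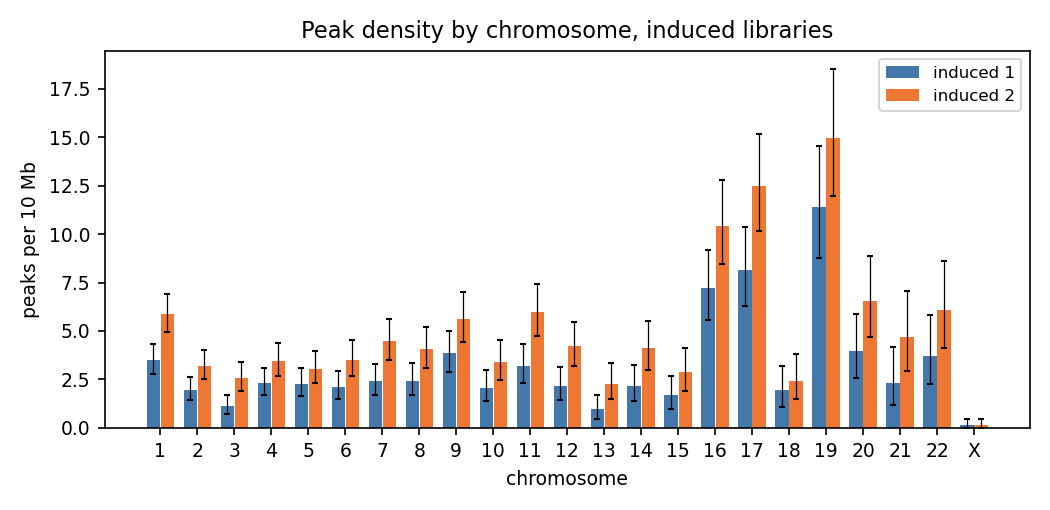
Peaks per 10 Mb (y axis) on each chromosome (x axis) in the induced libraries, with length taken as the furthest peak of the 4 lists and 95% Poisson intervals, which cover counting error only, as error bars. Chromosome 19 reached 11.4 and 15.0 peaks per 10 Mb, and chromosome X 0.131 in each library.

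Shared peaks were concentrated near the short-arm ends of some chromosomes. On the 18 chromosomes tested, 105 of 598 shared peaks (17.6%, 14.6 to 20.8) lay in the first 5 Mb, where uniform placement gave 25.01, a ratio of 4.20 (one-sided permutation of positions, p = 1e-04, the smallest that 10000 placements can give). Chromosomes 19 (18 peaks), 1 (17), 11 (16), 16 (16) and 4 (14) supplied most of them. The number lay above that expected from length on 12 of the 18. On chromosomes 2, 8 and 10 this was 1 peak against 0.761, 0.858 and 0.887 expected, and on chromosome 20 it was 2 against 1.67. Long-arm ends were not tested. Chromosomes 3, 9, 12, 18 and X had none, where at most 1.53 were expected on any of them. The ratio was 4.47 for shared peaks with a mean percentile of at least 75 and 3.99 for those under 50. The densest 1 Mb windows were on chromosome 1 from 1000001 to 2000000, with 10 shared peaks, and on chromosome 9 from 140000001 to 141000000, with 8. Windows with 7 each were the first of chromosome 11, the first of chromosome 19, and chromosome 9 from 139000001 to 140000000.

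Shared sites also lay close together. Summits at most 20 kb apart formed 27 runs of 2 or more peaks, holding 60 peaks, where uniform placement gave a mean of 4.12 runs and at most 10 (permutation of positions, p = 0.005, the smallest that 200 placements can give). Runs of 3 or more occurred in 4 regions. The region on chromosome 1 from 1098057 to 1111956 held 4 peaks, with folds of 3.30 to 16.7 in induced 1 and 3.50 to 16.0 in induced 2. The region on chromosome 11 from 2225223 to 2232696 held 4, with folds of 4.23 to 6.01 and 3.78 to 9.61. Chromosome 10 from 135060844 to 135074309 and chromosome 19 from 18794715 to 18809921 held 3 each. Uniform placement ignores regional differences in peak density, which the counts per chromosome and per window show.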

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

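The alternatives for the ratio of peak numbers, the chromosome ends and chromosome X, and the shifts by 5 to 100 kb, were chosen after seeing the data, and all others were planned. The difference in mean peak number was 1072.5 with all peaks and also under a replicate block (exact sign-flip p = 0.5, the smallest that 2 pairs allow). The numbers 1 and 2 are not stated to mark a shared day or batch, and the lists give no value for a site in a library without a peak, so pairing could not be checked. A fold of at least 5 brought the difference to 561.5 and the shared peaks from 661 to 342. That follows from the filter, since the median fold of both lists lies near 5. Leaving out 1 library gave differences of 815 to 1330, and no other alternative moved either number by over 1.5 times. The ratio of the means, 135, ranged from 98.2 to 216 with 1 library left out, and the highest value, without uninduced 2, follows from the 5 peaks of uninduced 1. When induced 2 was shortened to the 823 peaks of highest fold, 512 peaks of induced 1 were shared. Spearman's rho stayed between 0.571 and 0.585, and 9 to 11 uninduced peaks overlapped induced ones, under every setting run. The ratio for the first 5 Mb was 3.94 to 4.15 with 1 induced library left out, 2.40 for the first 10 Mb and 6.30 for the first 2 Mb. The X chromosome held 0.0295 to 0.0481 of the expected peaks in single lists, and 0.0578 at a fold of at least 5. The planned annotation, motif and gene-list results were not run, since no hg19 sequence was used. The lowest called pileups were 28 reads in induced 1, before the scaling down by 1.40 used for calling, and 17 in induced 2. Whether depth set these limits was not tested. A peak missing from 1 list is not shown to be absent there.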

Other observations

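The tests of explanations were all chosen after the patterns had been seen, and the criteria for leaky expression and for X copy number and gene density were changed after a first result. At the chromosome 6 site the change left the outcome as it was, for X it left open explanations that had first been excluded, and at the other uninduced peaks it left open leaky expression, whose needs had first been taken as met. In induced 2, a 1.26-fold peak on chromosome 21 at 9826067 to 9826356 had a control pileup of 404 reads, the only peak of that list above 100. The second list was the longer one in both conditions, by 1.63 times in induced and 2.2 times in uninduced cells. Uninduced 2 includes 4 peaks of low fold, and at a −log10 q of at least 5 the uninduced lists held 5 and 7 peaks. The inferred depth of induced 1 was 1.45 times that of induced 2. Its pileups were, however, scaled down by the ratio of 1.40 to its control before peaks were called. The depth ratio therefore does not say that induced 1 should have had the longer list.

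A wide peak on chromosome 6, from 135502324 to 135503572 in induced 2, was in 3 of the 4 libraries and did not follow induction. Leaky SNAIL1 expression would also place it in induced 1. There the level of induced 2 would be 252 reads scaled by depth, and 214 scaled by the pileup ratio of shared peaks. Both lie above the highest pileup in induced 1 (196), yet no peak is listed there. Extra copies of the region are argued against by a control pileup of 5.50 reads in induced 2, 0.786 of the median over that list's peaks. DNA carried into 3 of the libraries, or binding by another protein in these cultures, stays open: its width ranked 2 among the peaks of induced 2, which fits either.

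Chromosome X held 2 peaks in each induced list, for which a single copy of X is a candidate explanation, since it would give X sites lower pileups than autosomal sites. With pileup and background of every autosomal peak divided by 2, the genome-wide background as floor and the call limit at the 25th percentile of the list's −log10 p, 8.42 X peaks would remain in induced 1 and 15.6 in induced 2, against 29.2 and 44.2 with the limit first used, the list's lowest −log10 p (exact Poisson p = 0.00989 and 2.3e-05 for 2 or fewer at the stricter limit). At the mean autosomal density these values go against a single copy alone, as far as the assumed halving and call limit hold, whereas at the density of chromosome 13, the lowest of the autosomes, 2.82 and 7.60 X peaks would remain (exact Poisson p = 0.464 and 0.0188), against 9.80 and 21.5 with the limit first used (exact Poisson p = 0.00327 and 1.1e-07). Induced 2 thus had fewer X peaks than a single copy together with a low density of sites would leave, at each limit tried, and this combination stays open only through induced 1 at the stricter limits. The 2 observed X peaks of each list were counted without these limits. The weaker X peak of induced 1 (4.57-fold, −log10 q of 6.93) may miss the limit at the 25th percentile. The p given for induced 1 at that limit may therefore be too high. A low number of genes per length was set against chromosome 13, known for few genes. It had 2.27 peaks per 10 Mb (95% interval 1.48 to 3.33) in induced 2 and 0.960 (0.479 to 1.72) in induced 1. Among shared peaks it had 0.786 (0.359 to 1.49). The upper limits on X were 0.473, 0.473 and 0.365. The intervals were apart in both single lists, which goes against few genes alone, unless X has fewer still, which was not counted. They overlapped for shared peaks, of which X held 1. Overlapping intervals do not show equal densities, and shared peaks are a part of both lists. That comparison therefore neither excludes this explanation nor speaks for it.

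The uninduced peaks fall into more than one kind. Apart from the chromosome 6 site above, those shared with induced cells sat at the strong end of the induced lists, with a median percentile of 96.5 over 5 sites in induced 1 and 95.2 over 6 sites in induced 2 (permutation p = 0.00043 and 0.00012). Leaky SNAIL1 expression without doxycycline would favour strong sites, but 13 of the 15 named shared sites, among them the chromosome 17 site at 7165563 with 19.3-fold and 18.4-fold enrichment, were in no uninduced list, while the weaker chromosome 6 site near 169313392 was in both, with 9.06-fold and 5.28-fold enrichment against 10.2-fold and 8.73-fold in the induced lists. Leaky expression and background at fixed sites that does not depend on SNAIL1 may each account for these peaks and both stay open, since fixed sites may lie anywhere in the induced lists, where the lowest percentile in induced 2 was 63.2. The 4 low-fold peaks of uninduced 2 had at least 477 control reads, consistent with repeat sequence collapsed in the assembly.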
